A study of Homo sapiens with 7 samples.

How the data were processed

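Genomic DNA of SK-N-BE(2) cells, sheared to 300 bp, was used for selective chemical labelling of 5-hmC: a glucosyltransferase adds an azide-bearing glucose to 5-hmC, biotin is attached to it through a cleavable linker, and the fragments are captured on streptavidin and released, per the labels' protocols. The series has 7 samples: an input at 21% oxygen, which was not analysed here, and 1 captured library each at 0 h (21% oxygen) and at 6, 12, 24, 48 and 72 h (1% oxygen). Samples were grouped by the time and oxygen given in their labels.

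Each deposited list has 3 columns, the chromosome, start and end of each peak, and holds no height, fold enrichment, p, q or summit. BWA 0.7.17, MACS2, HTSeq and the build hg19 are named in the submitters' processing notes, without role or order. The threshold, and whether the input served as control, are not given in the sources used here. Each sample has its own list. Within a list no peaks overlapped. The narrowest peak differed between lists (226, 235, 231, 233, 232 and 242 bp from 0 to 72 h), so the lists were not all made with the same smallest width, and more reads or a better capture can lengthen a list with no change in the cells. Read depth is unknown, and no interval here allows for it.

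Peak number and covered length were set against hours by Pearson's r and Spearman's rho with exact two-sided permutation p over all 720 orders, adjusted by Benjamini-Hochberg over 5 measures. Peaks were called shared when they overlapped by at least 1 bp. Shares have 95% Clopper-Pearson intervals, and chance overlap is the mean of 20 random circular shifts within each chromosome. Overlapping peaks of all lists were merged into regions, and expected counts assume independent presence given each list's total. Peaks were counted by midpoint in 1 Mb bins of chromosomes 1 to 22 and X. A bin was called, by size alone, when its number differed from normoxia by at least 10 peaks and the ratio, with 0.5 added to both numbers and divided by the ratio of the totals, was at least 1.5 or at most its inverse. Since totals rose, the difference in peaks is reached more easily by higher than by lower bins. A form that takes the difference from the expected number was run first and is kept as an alternative. The rule set beforehand did not say which difference was meant, and that from normoxia was taken after this first run. Density deciles were set on the mean over all 6 lists. Arms were parted at the largest gap without peaks, with chromosomes 13, 14, 15, 21 and 22 taken as long arm, and the adjusted ratio divides an arm's number by the number its bins would have at the ratios of their deciles. In 250 kb bins covered length was used, for the 6424 bins with a mean of at least 8 kb. Relations over chromosomes have 100000 permutations.

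The gene table at hand is for the assembly GRCh38.p14, another build than that of the lists, so no gene positions were joined and it served only for the number of protein-coding genes per chromosome (19126 on the autosomes), divided by the position of the last peak. Annotation of peaks, peak number per gene and the 13 gene lists, with their cell type markers, all fixed before the data were examined, were therefore not run. Peak strength, and alternatives by q or fold, were not run because the lists hold neither. Named regions were to be the 5 with the highest score in each direction. Without scores, the widest peak was used in place of the score, and the midpoint in place of the summit. The gene density relation, the density deciles, the 250 kb bins, the arms and the named bins were chosen after the data were examined.

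Alternatives fixed before the data were examined were autosomes alone, peaks or regions merged over 300 bp, overlap of at least 0.5 of both peaks, midpoint inside the other peak, time rank without normoxia, the share of regions in common and 5 Mb bins. Added afterwards were peaks of at least 500 or 1000 bp, the same number of peaks per list with the widest first (which leaves the normoxia list, the shortest, whole), each list left out, covered length in place of number, 6 h as the reference and 250 kb bins. The form of the bin difference that was run first was kept as a further alternative. The computations were tested on simulated lists of 99900 peaks in all, where 11 of 11 quantities came back within 0.5%. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and Matplotlib 3.10.9 were used.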

Results

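The distribution of 5-hydroxymethylcytosine (5-hmC), an oxidation product of 5-methylcytosine made by the TET enzymes, was followed in SK-N-BE(2) cells over time in low oxygen. SK-N-BE(2) is an established neuroblastoma line that carries an amplified MYCN gene, a transcription factor of the MYC family. Cells were kept at 21% oxygen (normoxia, 0 h) or in 1% oxygen (hypoxia) for 6, 12, 24, 48 or 72 h. Fragments holding 5-hmC were labelled, captured and sequenced, and each time point is represented by 1 list of enriched regions (peaks). The 6 lists held 285292 peaks at 0 h, 292707 at 6 h, 294096 at 12 h, 312126 at 24 h, 336931 at 48 h and 352484 at 72 h. There was 1 library per time point, so no value has a replicate error, and any difference between 2 times is a difference between 2 libraries. Normoxia was sampled at 0 h alone, so an effect of low oxygen cannot be told apart from one of time in culture. Read depth is unknown, since the lists give positions without heights, scores or read counts.

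The first question was whether the number and extent of 5-hmC peaks changed with time in hypoxia. Peak number rose at each step, and the 72 h list held 23.6% more peaks than the normoxia list. The length covered by peaks was 147 Mb at 0 h, 157 Mb at 6 h, 154 Mb at 12 h, 165 Mb at 24 h, 179 Mb at 48 h and 192 Mb at 72 h, which is 30.9% more at the last time than at the first. The smallest step in number was from 6 to 12 h, with 1389 more peaks, and the largest was from 24 to 48 h, with 24805 more. Peaks of at least 1000 bp numbered 22061 in normoxia and 30562 at 72 h.

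Peak number increased with hours in hypoxia over the 6 lists, with Pearson's r = 0.993 (exact two-sided permutation p = 0.00139, adjusted p = 0.00694) and Spearman's rho = 1 (exact permutation p = 0.00278, adjusted p = 0.0139). Without the 2 times farthest from the median time, r was 0.977 over 4 lists. For covered length, r was 0.989 (exact permutation p = 0.00278, adjusted p = 0.00694) and rho was 0.943 (exact permutation p = 0.0167, adjusted p = 0.0278), and r without those 2 times was 0.909. The test of rho for covered length was no longer passed when the list of 0, 24, 48 or 72 h was left out (rho = 0.9, exact permutation p = 0.0833 for each). Median peak width was 395 bp at 0 h and 421 bp at 72 h, and its relation to time did not pass the test (r = 0.810, exact permutation p = 0.0514, adjusted p = 0.0642; rho = 0.657, exact permutation p = 0.175, adjusted p = 0.219; r = 0.474 without the same 2 times). The narrowest peak of a list ranged from 226 bp at 0 h to 242 bp at 72 h. Benjamini-Hochberg adjustment was over 5 measures, and the lists do not show how sensitive peak calling was in each library.

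**Figure D1:**
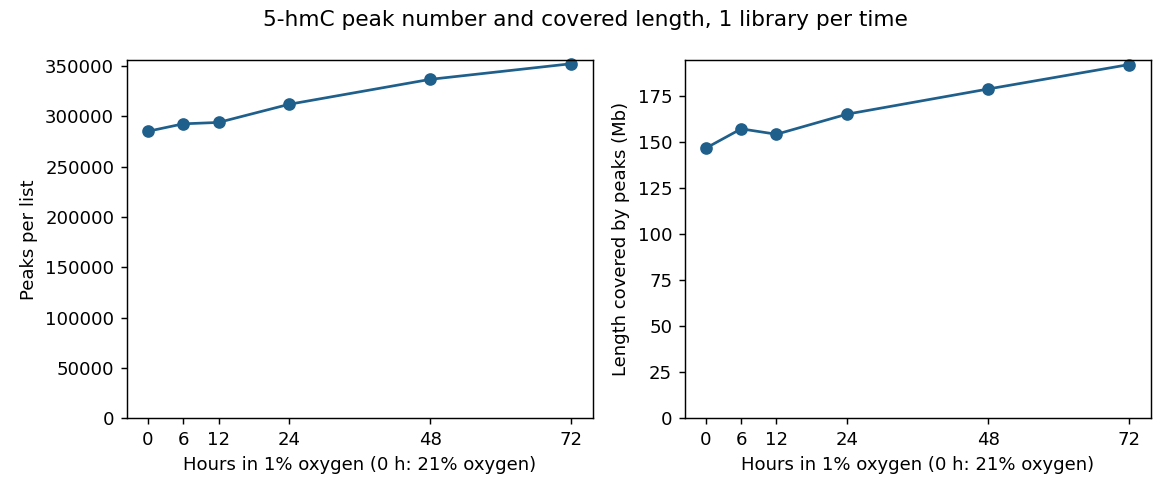
Number of 5-hmC peaks (left) and length covered by them in Mb (right) against hours in 1% oxygen, with 1 point per library and no error bars because there was 1 library per time. The number goes from 285292 at 0 h to 352484 at 72 h, and the covered length from 147 to 192 Mb, with a dip between 6 and 12 h.

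The next comparison asked which peaks of hypoxic cells were already present in normoxia. Most normoxia peaks were found again at every time, and the later hypoxia lists held more peaks with no counterpart in normoxia. Of the 72 h peaks, 70.3% overlapped a normoxia peak (95% Clopper-Pearson interval 70.1 to 70.4%), against 82.4% of the 6 h peaks (82.2 to 82.5%). In the other direction, 89.8% of normoxia peaks overlapped a 72 h peak (89.7 to 89.9%) and 86.0% overlapped a 6 h peak (85.9 to 86.1%). Peaks placed at random by circular shifts overlapped far less often, at 9.74% for the 72 h list against normoxia and 12.3% for the reverse.

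Between these times, the share of hypoxia peaks overlapping normoxia was 82.5% at 12 h, 79.3% at 24 h and 74.0% at 48 h. The 72 h list held 104729 peaks (29.7%) without a normoxia overlap, and the normoxia list held 29011 peaks (10.2%) without a 72 h overlap. Part of this is seen between any lists. Between the hypoxia lists of 6 and 12 h, of similar length, 14.8% of 6 h peaks and 14.6% of 12 h peaks had no overlap. Without a normoxia overlap were 17.6% of 6 h peaks. Peaks without a counterpart were narrow. Their median width was 311 bp among 72 h peaks, against 497 bp for those shared with normoxia, and 267 bp among normoxia peaks, against 417 bp for those shared with 72 h. Of the 30562 peaks of at least 1000 bp at 72 h, 137 (0.448%) had no normoxia overlap, and of the 22061 such normoxia peaks, 4 had no 72 h overlap. The intervals cover counting error only.

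Peaks of all lists were then merged into 415474 regions, to describe which sites were kept, gained or lost. A total of 194585 regions (46.8%) were present in all 6 lists, where independent presence would give 47529. In all 5 hypoxia lists and not in normoxia were 12439 regions, and in normoxia alone 7637. Regions that a single hypoxia list lacked numbered 7119 for 6 h, 6940 for 12 h, 4010 for 24 h, 2666 for 48 h and 4092 for 72 h, so that part of the 12439 is expected from the drop-out of regions from a single list. A further 5775 regions were present from 12 h on, 8058 from 24 h on and 14984 at 48 and 72 h alone. Regions seen in a single hypoxia list numbered 7182 at 6 h, 6593 at 12 h, 8898 at 24 h, 14277 at 48 h and 29605 at 72 h. Regions present from 0 h that left at one time and stayed away numbered 15373, including the 7637 in normoxia alone and the 4092 that only the 72 h list lacked. Independent presence would give 28249 regions in all 5 hypoxia lists without normoxia, and 440 in normoxia alone. Presence was not independent between lists, so these expected counts do not measure a change in hypoxia. The 6 h list departed likewise, with 7119 regions that it alone lacked (25200 if independent) and 7182 in it alone (494 if independent).

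With only peaks of at least 500 bp in all lists, 5523 regions were in all 5 hypoxia lists and not in normoxia, and 2712 were in normoxia alone. Keeping the 285292 widest peaks of each list gave 7938 and 12012, but this leaves the normoxia list whole and removes narrow peaks from the hypoxia lists alone (to a floor of 298 bp at 72 h, against 226 bp at 0 h), so shifts in this direction are expected from the construction. Among regions absent in normoxia and present at all 5 hypoxia times, the widest 72 h peaks lay, in hg19, on chromosome 2 from 13669028 to 13670827 (1800 bp), chromosome 10 from 126788260 to 126789952 (1693 bp), chromosome 3 from 186588294 to 186589941 (1648 bp), chromosome 9 from 138937959 to 138939509 (1551 bp) and chromosome 6 from 43754633 to 43756106 (1474 bp). Among regions in normoxia alone, the widest peaks lay on chromosome 18 from 25696843 to 25697789 (947 bp), chromosome 4 from 99650637 to 99651265 (629 bp), chromosome 13 from 94490895 to 94491514 (620 bp), chromosome 9 from 36538867 to 36539485 (619 bp) and chromosome 19 from 2434229 to 2434841 (613 bp). Gene annotation of these regions was not used here.

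By the Jaccard index, lists that lay closer in time were more alike. The Jaccard index, the shared length over the total length of a pair of lists, was 0.677 for 0 and 6 h and 0.606 for 0 and 72 h, and it was highest for 48 and 72 h, at 0.706. Over the 15 pairs, the index fell with distance in time order (Spearman's rho = -0.891, exact two-sided permutation p = 0.00278 over the 720 orders of the 6 lists). This is the smallest two-sided p that a rank test on 6 lists allows. Pairs share lists, so the lists and not the pairs were permuted. The index cannot exceed the shorter covered length over the longer, and covered length rose from 147 Mb at 0 h to 192 Mb at 72 h. Part of the fall is therefore built in by list length, and the test does not separate that part. For the share of normoxia peaks found again the order differed, with 86.0% at 6 h and 89.8% at 72 h. The longer 72 h list favours this, with a chance overlap of 10.2% at 6 h and 12.3% at 72 h. In the other direction the order was that of the index, with 82.4% of 6 h peaks and 70.3% of 72 h peaks overlapping normoxia.

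The location of the added peaks was compared across chromosomes and 1 Mb bins. Bins with few peaks gained proportionally most. In the sparsest decile of bins, peak number at 72 h was 1.69 times that at 0 h, from 1088 to 1836 peaks, and in the densest decile it was 1.10 times, from 73252 to 80656. Covered length rose 1.88 times in the sparsest and 1.19 times in the densest decile. At 6 h the corresponding ratios of peak number were 1.06 and 1.01. The 5 sparsest deciles held 20.7% of peaks at 0 h and 23.9% at 72 h, or 22.6% at 72 h with the 285292 widest peaks of each list.

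**Figure D2:**
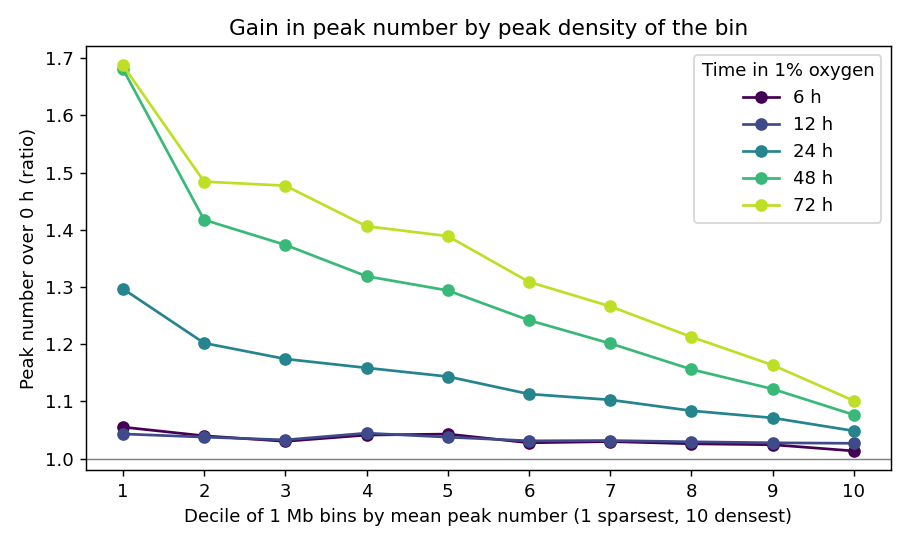
Ratio of peak number to that at 0 h (vertical axis, no unit) for 10 groups of 1 Mb bins ordered by mean peak number over the 6 lists (horizontal axis), with 1 line per hypoxia time. At 72 h the ratio goes from 1.69 in the sparsest decile to 1.10 in the densest, while the 6 h line stays between 1.01 and 1.06.

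By the fixed rule of size, 121 of 2843 bins were higher at 72 h than in normoxia relative to the totals and 1 was lower. At 48 h 81 bins were higher, at 24 h 12, at 12 h 1 and at 6 h 0, and the only lower bin before 72 h was 1 at 6 h, on chromosome 11. Of the bins higher at 72 h, 60 were also higher at 48 h, but both sets share the normoxia list. With 6 h as the reference, 90 bins were higher at 72 h, of which 59 were also higher against 0 h, and these 2 sets share the 72 h list. Independent calls would give 3.45 bins higher at both 48 and 72 h, a value that ignores the shared normoxia list. No expected overlap that allows for a shared list was computed for either pair of sets. Ranked by the difference of square roots, the leading bins among those above 1 at all 5 hypoxia times were chromosome 8 from 84 to 85 Mb, with 34 peaks at 0 h and 95 at 72 h, chromosome 13 from 55 to 56 Mb, with 29 and 83, chromosome 16 from 60 to 61 Mb, with 24 and 73, and chromosome 2 from 195 to 196 Mb, with 14 and 52. The bin that was lower at 72 h was the 1 Mb bin of chromosome X that starts at 110 Mb, with 68 peaks at 0 h and 52 at 72 h. These bins were named after their values were seen. With the 285292 widest peaks of each list, 45 bins were higher and 2 lower, and with peaks of at least 500 bp 226 were higher and 1 lower. The form run first, with the difference taken from the expected number, gave 106 higher and 2 lower at 72 h.

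Gene-poor chromosomes gained more. The ratio of peak number at 72 h to that at 0 h was 1.31 on chromosome 4 and 1.30 on chromosome 13, and 1.15 on chromosome 19 and 1.13 on chromosome 22. Over the 22 autosomes, the ratio fell with the number of protein-coding genes per Mb (Pearson's r = -0.614, permutation p = 0.00052, adjusted p = 0.00104; Spearman's rho = -0.736, permutation p = 0.00022, adjusted p = 0.00044). Without chromosomes 17 and 19, which lie farthest from the median gene density, r was -0.727. Against normoxia peaks per Mb, r was -0.584 (permutation p = 0.00406, adjusted p = 0.00406) and rho -0.636 (permutation p = 0.00187, adjusted p = 0.00187), and r without chromosomes 17 and 18 was -0.630. These 2 relations form the family, and chromosomes of 1 pair of libraries are not independent replicates. With the 285292 widest peaks of each list, the relation to gene density no longer passed the test (r = -0.396, permutation p = 0.0639).

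Against the general rise, a stretch of chromosome 2 from 16 to 16.75 Mb lost peaks. It held 145 peaks covering 106 kb at 0 h, 110 peaks covering 72.7 kb at 48 h and 123 peaks covering 86.8 kb at 72 h. Covered length there was 6.39% lower at 6 h than at 0 h, 31.1% lower at 48 h and 17.8% lower at 72 h. The bins directly on both sides rose, from 27.4 to 33.6 kb and from 17.8 to 25.7 kb between 0 and 72 h. The edges of the stretch are those of the 250 kb bins. In 50 kb windows the loss at 72 h lay from 16.05 to 16.6 Mb, with ratios to 0 h, relative to the totals, of 0.400 to 0.649. The other windows of the stretch rose between 0 and 72 h, from 4.37 to 6.16 kb in its first window and from 2.69 to 3.08 kb in its last. Among 4099 runs of 3 adjacent 250 kb bins, this run had the lowest ratio to 0 h at 24, 48 and 72 h, and the stretch was singled out after its values were seen. The widest peak in it measured 6431 bp at 0 h and 2642 bp at 72 h.

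**Figure D3:**
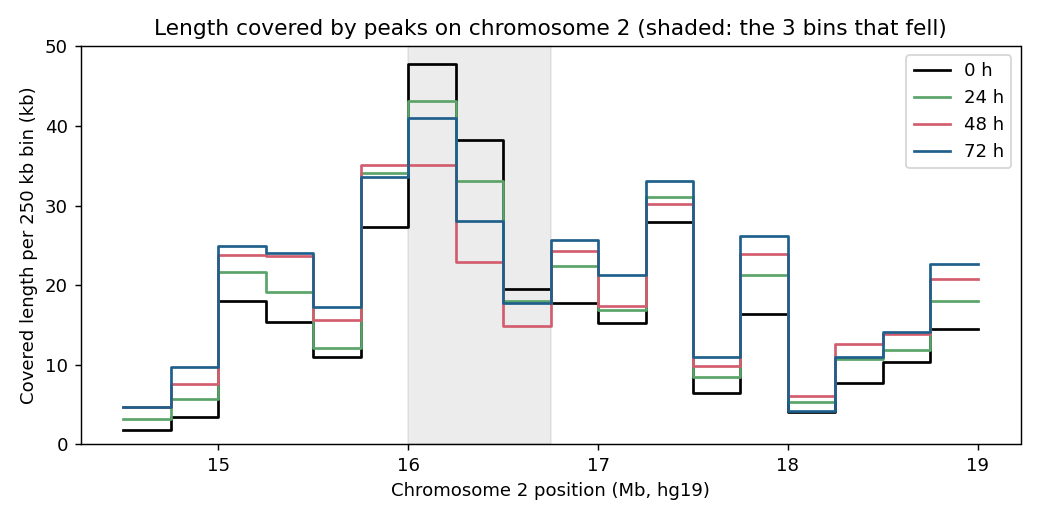
Length covered by 5-hmC peaks in kb per 250 kb bin (vertical axis) along chromosome 2 in Mb of hg19 (horizontal axis), with 1 line each for 0, 24, 48 and 72 h and the stretch from 16 to 16.75 Mb shaded. In the shaded bins the 48 and 72 h lines lie below the 0 h line, and in the bins directly beside them they lie above it.

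The short arm of chromosome 11 also had fewer peaks relative to the rest of the genome, from 6 h on. It held 3991 peaks at 0 h, 3629 at 6 h and 4567 at 72 h. After adjustment for peak density, its ratio to 0 h was 0.884 at 6 h, 0.896 at 12 h, 0.921 at 24 h, 0.877 at 48 h and 0.881 at 72 h, the lowest of 41 chromosome arms at each time. The other arms lay between 0.943 and 1.05 at 6 h, and between 0.884 and 1.05 at 72 h. All 10 of its 5 Mb bins were below 1 at 6 h, as were 12 of 16 on the long arm. The arm was singled out after its values were seen.

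**Figure D4:**
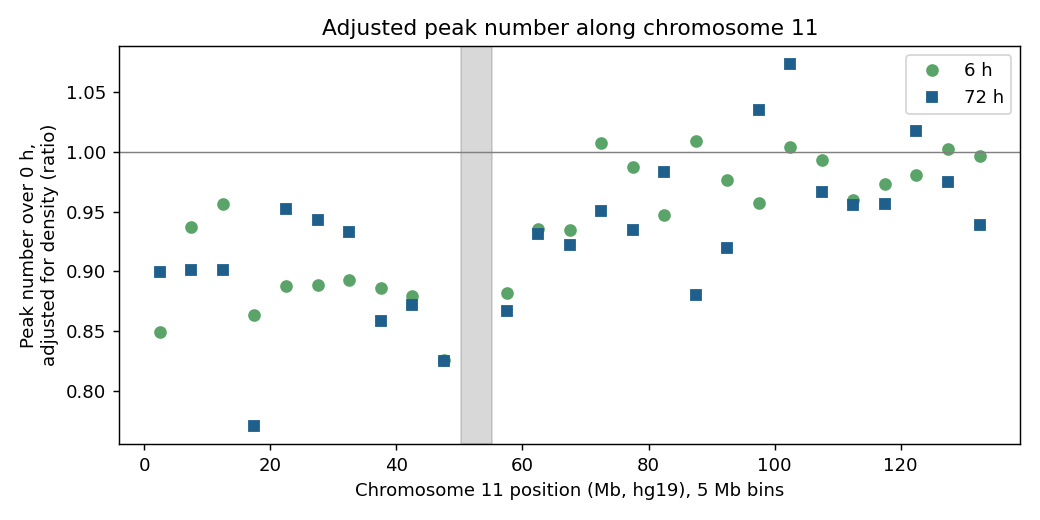
Ratio of peak number to that at 0 h, adjusted for peak density (vertical axis, no unit), in 5 Mb bins along chromosome 11 in Mb of hg19 (horizontal axis) at 6 and 72 h, with the peak-free gap between the arms shaded. All 10 bins of the short arm lie below 1 at 6 h, and 12 of 16 of the long arm do.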

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

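Peak number kept its rise with time under all alternatives run, as did the decline of list similarity with distance in time (rho from -0.953 to -0.636 with each list left out). Covered length lost its side of the threshold with time rank and no normoxia (rho = 0.9, exact permutation p = 0.0833), and likewise without the list of 0, 24, 48 or 72 h; rho ranged from 0.9 to 1 with each list left out, and 5 lists leave a smallest p of 0.0167. Of 74 alternatives, 44 kept their value or side and 0 reversed a sign. Counts and shares have no sign to reverse, so this covers the correlations alone. Regions in all 5 hypoxia lists without normoxia (12439) outnumbered those in normoxia alone (7637). With the 285292 widest peaks of each list that order turned round (7938 against 12012), which the construction favours, as set out below.

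The share of 72 h peaks overlapping normoxia, and the reverse, were 70.5% and 89.9% on autosomes, 62.3% and 77.0% with overlap of at least 0.5 of both, and 66.9% and 88.3% by midpoint. Chosen after seeing the data, the 285292 widest peaks of each list gave 79.2% and 82.6%, and peaks of at least 500 bp against all peaks of the other list 94.1% and 99.2%. Regions in all 5 hypoxia lists without normoxia, and in normoxia alone, numbered 5523 and 2712 with peaks of at least 500 bp, and 7938 and 12012 with the widest peaks. The latter choice removes narrow peaks from the hypoxia lists alone, with a floor of 298 bp at 72 h against 226 bp at 0 h, so a lower first count and a higher second one are expected from the construction. Bins higher at 72 h numbered 3 at 5 Mb, 226 with peaks of at least 500 bp, 45 with the widest peaks and 521 of 250 kb by covered length. Bins lower at 72 h numbered 0 at 5 Mb, 0 by covered length, 2 with the widest peaks, 5 of 250 kb and 2 with the difference taken from the expected number. The relation to gene density was r = -0.396 (permutation p = 0.0639) with the widest peaks. The causes of these changes were not tested. Alternatives by q or fold, and those that need gene positions, were not run. Depth is unknown, so its effect on list length has no value here.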

Other observations

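The tests of merging, of calling sensitivity in sparse bins, of the 50 kb windows and of distance between peaks were set before their results were seen. The other tests on chromosome 2, including that of 72 h against 6 h, whose bounds were set with its value known, that without 3 windows and that of window runs, which came after the other 2 window tests, and those on chromosome 11 were chosen only after the result was seen, and the comparison with lost peaks was added after the distance of gained peaks was known.

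Peaks also widened at sites that every list held. In 155718 regions with exactly 1 peak in each of the 6 lists, the median width was 434 bp at 0 h and 502 bp at 72 h, and 71.2% of them were wider at 72 h than at 0 h. After each list's narrowest width was subtracted, 65.5% were wider at 72 h and 34.1% narrower. Among the 6424 bins of 250 kb with a mean of at least 8 kb covered, the highest ratio of covered length at 72 h to 0 h, relative to the totals, was 2.58 on chromosome 6 from 11.25 to 11.5 Mb, with 8.43 kb at 0 h and 28.5 kb at 72 h. Genes in it were not looked up, since no positions of this build were used here.

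Later lists gained proportionally most in sparse 1 Mb bins. Merging of neighbouring peaks in dense bins would leave covered length to rise there at least as much, but its factor in the densest decile was 0.631 of that in the sparsest, which argues against merging. More sensitive calling in the later libraries could add weak peaks in sparse bins. The same number of peaks was then taken per list, for which only hypoxia lists were cut. The share in the 5 sparsest deciles was still 1.83 percentage points higher at 72 h than at 0 h, between the bounds of 1 and 2 set beforehand. Calling sensitivity and a change in the cells therefore cannot be told apart without reads or replicates. With normoxia at 0 h alone, such a change could follow time in culture as well as hypoxia.

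The loss on chromosome 2 from 16 to 16.75 Mb was 17.8% of covered length at 72 h against 0 h, in a stretch picked for it, and 48 h against 0 h gives the same stretch as the lowest of 4099 runs. More sensitive calling as the whole cause is argued against by 72 h against 6 h, for these late lists only. That pair shares no list with 48 h against 0 h, although 72 h against 0 h picked the stretch too. Covered length was 12.2% lower and the ratio relative to the totals 0.718 (95% interval 0.562 to 0.919 from counts), the lowest run. The 95% intervals of these ratios take counting error from peak numbers alone. They leave out variation in peak width and between libraries, so they may be too narrow for covered length. Of the 5 other pairs that share no list with 48 h against 0 h, the stretch ranked lowest in 1 and 7, 134, 191 and 1249 in the rest. The last was from 6 to 12 h, where the median run fell too. Ratios were 0.980 from 6 to 12 h, 0.908 from 6 to 24 h and 0.926 from 12 to 24 h, each with an interval that held 1. So did the interval from 24 to 72 h (ratio 0.791). Tests of loss at a few sites were mixed and leave it open. Runs were counted of 50 kb windows at or below the inverse of 1.5. At 72 h against 0 h, on which the stretch was picked, 11 windows were consecutive and at most 5 elsewhere. Among pairs sharing no list with it, the run was longer than elsewhere at 48 h against 6 h (8 against 4) and 12 h (10 against 3). Both hold the 48 h list, and 48 h against 0 h picked the stretch too. The run was not longer from 6 to 12 h (1 against 3), 6 or 12 to 24 h (0 against 3 each) or 24 to 48 h (3 against 4). At 72 h it was 4 against 3 from 6 h, 4 against 4 from 12 h and 2 against 4 from 24 h. Of the 15 windows, 80% were below the ratio of totals at 72 h against 0 h (95% Clopper-Pearson interval 51.9 to 95.7%). This met the bound of at least 8 of 10 set beforehand against loss at a few sites. The interval also reaches below 6 of 10, the bound set for such loss, and the stretch was picked on this pair. The window share therefore did not decide. Without the 3 windows of largest loss at 48 h, the ratio at 72 h against 6 h was 0.751 (95% interval 0.557 to 1.01). That interval holds 1, the outcome set for loss at a few sites. The 3 consecutive 250 kb bins fell while the bins on both sides rose, but these bins were picked for falling. Fewer copies of amplified DNA in the later cultures may lower covered length in this way. This and a change of 5-hmC on unchanged DNA cannot be told apart without copy number, and whether the stretch holds the amplified MYCN gene of this line was not determined here.

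On the short arm of chromosome 11, 100% of 5 Mb bins were below 1 at 6 h, as fewer copies of the arm in the hypoxia cultures would give, but 75% of the bins of the long arm were too, above the bound set for it. A response that grows with time in hypoxia would lower the ratio further, and it changed by -0.00279 from 6 to 72 h, where the other arms' changes had an SD of 0.0313. Neither explanation is settled by these values, and an unusual normoxia library, the common reference, could give the same step and was not tested apart.

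A hypothesis was that gained 5-hmC may spread from existing peaks. The median distance of 72 h peaks without normoxia overlap to the nearest normoxia peak was 2.24 kb, 0.498 of that of random positions in the same 1 Mb bins. Normoxia peaks without 72 h overlap, which cannot have spread, lay at 0.363 of the random distance to 72 h peaks. Clustering of peaks in general therefore gives a ratio as low, and the test does not single out spread.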
